A study of Homo sapiens with 2 samples.

How the data were processed

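RNA of 2 MCF-7 lines, a control with the pLKO.1 vector and a stable SREBP1 knockdown, was measured on 1 array each. The control is titled as a hairpin control and its genotype label names only the vector, so whether it carries a non-targeting hairpin is not settled. Per the labels' protocols, total RNA was extracted with a column kit including a DNase step, and biotin-labelled cDNA was prepared with a whole-transcript kit and hybridised to Affymetrix arrays. Per the submitters' processing notes, the authors used RMA in Affymetrix Expression Console. RMA corrects background, quantile normalises the probes across arrays and summarises the probes of each probe set by median polish. The authors deposited the result as log2 intensities with up to 6 decimals, and the log2 scale was inferred from the range of 1.73 to 13.8. The software version, the arrays normalised together and any filter are not given in the sources used here. Scanner files, detection calls and probe-level data were not used here, so no background bound could be set for a dim probe set. RMA shares information between arrays, and 1456 of the 28832 probe sets (5.05%) held exactly the same value in both, at a median of 3.79. Of the genes past the dim filter, 116 did so.

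Probe sets were named through an annotation table of the array platform, in which 21029 of the probe sets appear. Of all probe sets, 19294 carried 1 gene symbol, 1735 carried several and 7803 are unnamed here. Symbols were updated through the Entrez gene ID to the RefSeq annotation of GRCh38.p14, which matched 19263 of the one-gene probe sets; the other 31 kept the table's symbol. Only one-gene probe sets entered the gene comparisons, and the probe sets of a gene were averaged, which gave 18373 genes, 683 of them with more than 1 probe set. No build is named for the array, so no coordinates are given. Gene span and gene order were taken from the same RefSeq table as properties of each gene.

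All computations used the deposited log2 values with no further normalisation. A gene was retained when its higher array value reached 6.33, the median of the one-gene probe sets over both arrays, which left 9402 genes. Because each group holds 1 array, no p-value was computed and genes were counted by a rule of size, a difference of at least 1.5-fold (0.58 on the log2 scale). Gene lists were described by the median over retained members, an exact binomial interval of that median from order statistics at 95% confidence, and the percentile of the median among 10000 random lists drawn from retained genes within 20 intensity bins. These percentiles describe the 2 arrays and are not tests of the knockdown. A list too short to reach 95% confidence was given the range of its members in place of the interval. The local spread of a gene was the scaled median absolute deviation of the differences of the 500 genes nearest in mean value. It includes real differences between the lines. Genes named in the text were SREBF1, SREBF2, MIR33A and MIR33B, the 15 protein-coding genes with the largest increase and the 15 with the largest decrease among retained genes, and up to 4 members of each list with the largest absolute difference. Genes named outside this rule are marked as such. The groups, the rule, the 23 lists and the alternative settings below except the last were fixed before the data were examined. A further 7 lists, used only for the closing observations, were written after the main results were seen.

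The alternative settings were centring of each array on its median, removal of a lowess trend (span 0.3) on intensity, quantile normalisation of the 2 arrays, no dim filter, a filter at the 70th percentile (7.43), the brightest or the least changed probe set per gene, a 2-fold threshold, a threshold of 3 local spreads, and the list mean. Removal of a lowess trend on log10 gene span was added after seeing the data. A span was found for 99.9% of retained genes. The method was tested on simulated differences for the 9402 genes of this comparison with a spread of 0.144, 100 genes changed 2-fold and 100 changed 3-fold. The size rule recovered 100% of each, and 0 of the unchanged genes passed it. Of 200 simulated unshifted lists of 25 genes, 4% lay outside the central 95% of random lists, and a list shifted by -0.2 lay below all random lists. The simulated genes varied independently with the same normal spread, whereas the local spread of a dim gene such as ART4 was 0.208. The simulation therefore gives no rate of false calls in these arrays and does not cover lists whose members vary together. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.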

Results

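Gene expression was measured in MCF-7 cells, an established oestrogen receptor-positive human breast cancer line, after stable knockdown of SREBP1. SREBP1, encoded by SREBF1, is a transcription factor that activates genes of fatty acid synthesis. A control line carrying the pLKO.1 lentiviral hairpin vector and a line carrying a hairpin against SREBP1 in the same vector were each hybridised to 1 whole-transcript oligonucleotide array, so the series holds 2 arrays and 1 array per group. The labels do not settle whether the control vector is empty or holds a non-targeting hairpin, so every difference is against a control of either kind. The study asked which genes differ in expression between the knockdown line and its control. The deposited values were log2 intensities of 28832 probe sets, which ran from 1.73 to 13.8 in the control array and from 1.73 to 13.7 in the knockdown array. With no replicate there was no test of any difference and no replicate error. Every difference below is the knockdown array minus the control array on the log2 scale, and it describes these 2 arrays. The number of arrays limits the precision of every value.

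SREBF1, the targeted gene, was lower in the knockdown array. Its only probe set read 7.39 in the control and 6.46 in the knockdown, a difference of -0.93, so the knockdown value was 52.5% of the control value. The difference was 6.58 times the local spread, which is the scaled median absolute deviation of the differences among the 500 genes nearest in intensity. SREBF1 ranked 15th among the 9402 genes retained after the dim filter, counted from the gene with the largest decrease. A stricter filter of 7.43 removes it. SREBF2, which encodes the related factor SREBP2 of cholesterol synthesis, read 7.88 in the control and 7.86 in the knockdown. The probe set of MIR33A, a microRNA encoded within SREBF2, read 3.61 in both arrays, below the dim filter. No probe set used here names MIR33B alone, so the microRNA within SREBF1 itself was not analysed.

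The 2 arrays differed at few genes. Among the 9402 genes whose higher array value reached 6.33, the median of all one-gene probe sets, 61 were at least 1.5-fold higher and 46 at least 1.5-fold lower in the knockdown array. The remaining 98.9% lay within 1.5-fold, and the central 95% of differences ran from -0.33 to 0.37. At a 2-fold threshold the counts were 14 higher and 12 lower, and a threshold of 3 local spreads gave 146 higher and 115 lower. Over all probe sets the arrays correlated with Pearson's r = 0.996, across probe sets, which are not independent replicates. Where a gene had 2 probe sets, as 296 of the retained genes did, the probe sets' differences lay a median of 0.059 apart and the 90th percentile of that gap was 0.312. Of the 107 genes past the 1.5-fold threshold, 3 were read by more than 1 probe set.

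**Figure D1:**
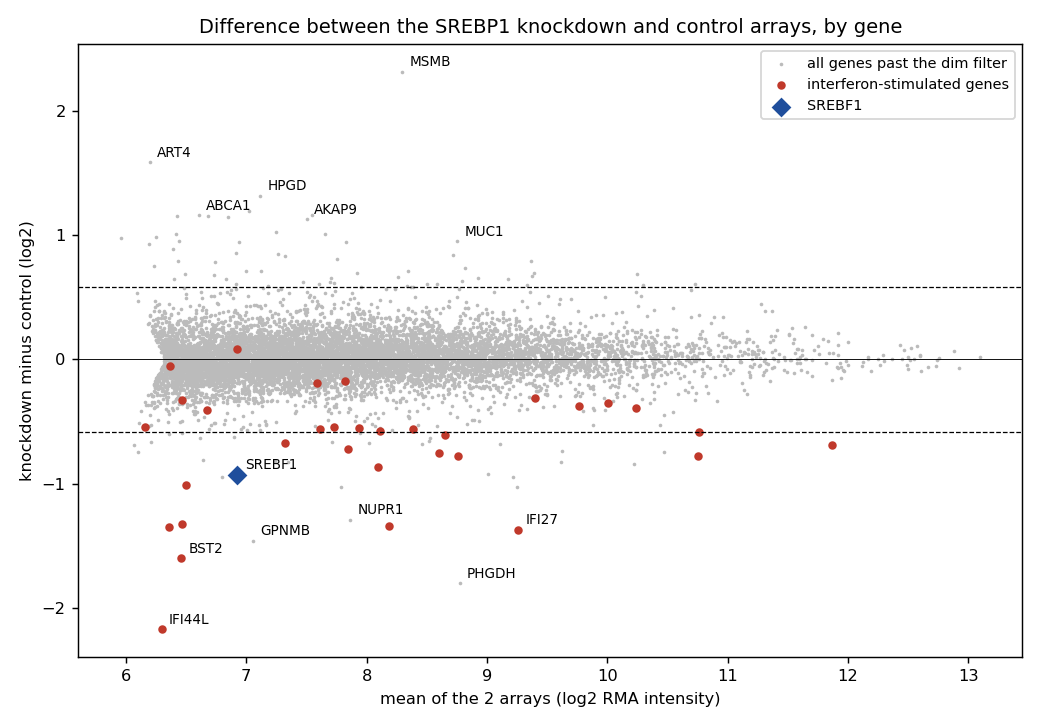
Difference between the knockdown and control arrays (log2, y axis) against the mean of the 2 arrays (log2 RMA intensity, x axis) for the 9402 genes past the dim filter, 1 point per gene, with 1.5-fold marked by dashed lines. SREBF1 (diamond) lies at -0.93, and 31 of the 32 interferon-stimulated genes (red) lie below 0, down to -2.17 for IFI44L.

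The genes with the largest decreases were led by IFI44L, one of several from the list of interferon-stimulated genes described below. It was 4.50-fold lower, at 7.38 in the control and 5.21 in the knockdown. BST2 (tetherin, which holds budding virus at the cell surface) was 3.03-fold lower, IFI27 2.59-fold, OAS2 2.54-fold, IFIT1 2.53-fold, DDX60 2.51-fold and USP18, a negative regulator of interferon signalling, 2.01-fold. PHGDH, the first enzyme of serine synthesis from glucose, was 3.48-fold lower, at 9.68 in the control and 7.87 in the knockdown. NUPR1, a stress-induced nuclear protein, was 2.44-fold lower and ASS1, an enzyme of arginine synthesis, 1.92-fold lower. GPNMB, a transmembrane glycoprotein, was 2.75-fold lower, and LGALS3BP, a secreted galectin-binding protein, was 2.04-fold lower. RCN1, a calcium-binding protein of the endoplasmic reticulum, was 2.03-fold lower and KLHL4 1.93-fold lower. USP18 shares sequence with USP41P, and a second probe set assigned to both genes differed by -1.05.

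The gene with the largest increase was MSMB, which encodes a secreted prostate and mucosal protein. It was 4.97-fold higher, at 7.14 in the control and 9.45 in the knockdown. HPGD, which inactivates prostaglandins, was 2.49-fold higher and PLA2G10, a secreted phospholipase, 2.29-fold higher. GPX2, a glutathione peroxidase of epithelia, was 2.24-fold higher. ABCA1, which exports cholesterol from cells, was 2.24-fold higher, at 6.03 in the control and 7.19 in the knockdown. PDK4, a kinase that restrains entry of pyruvate into the citric acid cycle, was 2.23-fold higher, and HSD17B11, a lipid droplet-associated dehydrogenase, was 2.22-fold higher. MUC5B, a gel-forming mucin, was 2.02-fold higher. The others among the 15 largest were ART4 (3.0-fold), SPOCK1 (2.23-fold), AKAP9 (2.19-fold), CAPN13 (2.04-fold), C12orf60 (2.01-fold), CCDC83 (1.98-fold) and SPINK7 (1.97-fold). The control values of ART4, ABCA1, PDK4, SPOCK1, HSD17B11, C12orf60, CCDC83 and SPINK7 lay below the dim filter, as did the knockdown values of IFI44L, BST2, OAS2, DDX60 and USP18. No detection calls were used here, so folds of these genes compare a measured value with a dim one. The stricter filter of 7.43 removes all of these genes, IFI44L and BST2 among them, and also KLHL4.

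**Figure D2:**
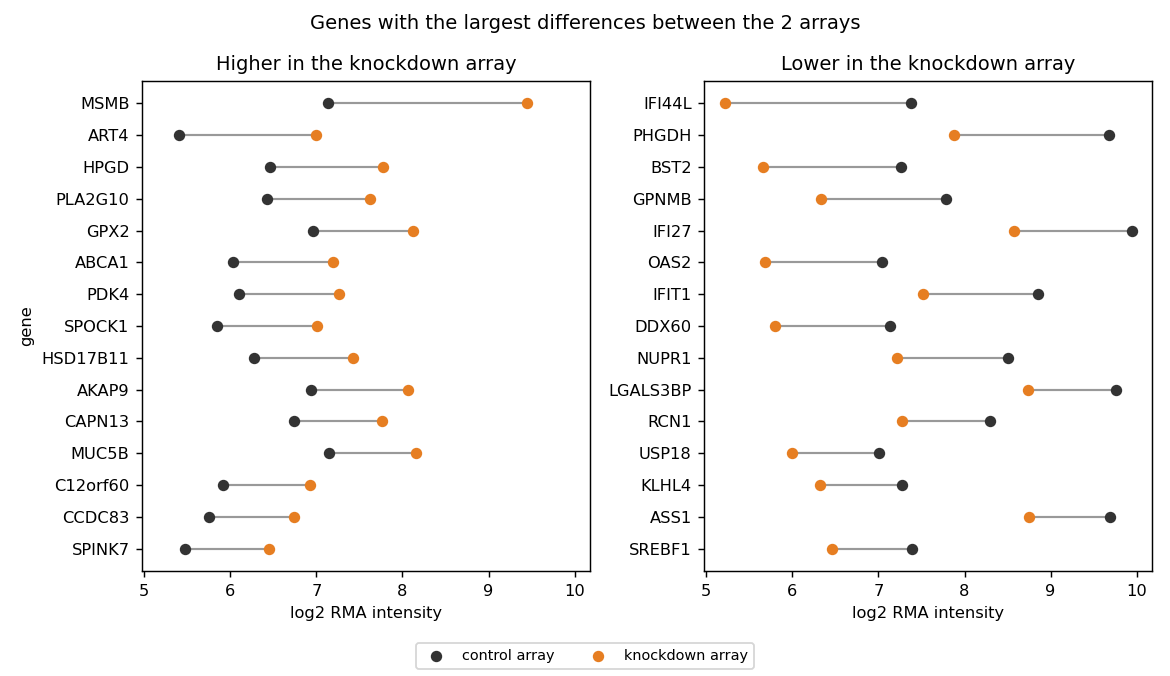
Log2 RMA intensity (x axis) in the control array (dark) and the knockdown array (orange) for the 15 protein-coding genes with the largest increase (left) and the 15 with the largest decrease (right). Each point is a single array; MSMB goes from 7.14 to 9.45 and IFI44L from 7.38 to 5.21.

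The 23 gene lists fixed before the data were examined were then compared with random lists of the same size, matched on mean intensity. For each list the median difference of the members past the dim filter is given with its exact binomial 95% interval over members, which are not independent of each other, and with its percentile among 10000 random lists. Of the 23 lists, 4 lay outside the central 95% of random lists, where 1.15 would lie outside if all genes varied independently. Members of a list can vary together and some lists share members, so these numbers do not show an excess over chance.

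The interferon-stimulated genes stood farthest from the rest. Their 32 members past the dim filter had a median of -0.58 (interval -0.77 to -0.40), lower than that of all 10000 random lists. Of these, 16 were at least 1.5-fold lower, none was 1.5-fold higher, and 31 lay below 0, with ISG20 at 0.08 the exception. They made up 34.8% of the 46 genes with a 1.5-fold decrease. Abundant members were included, with IFI27 at 9.95 in the control and 8.57 in the knockdown. Among members named outside the rule after their values were seen, IFITM1 differed by -0.77, OAS1 by -0.78, IFI6 by -0.69 and ISG15 by -0.56. IRF9 and IRF7, transcription factors of the pathway likewise named after their values were seen, differed by -0.31 and -0.40. The inflammatory signalling list of NF-kB targets and cytokines had a median of -0.06 over 8 members (interval -0.14 to 0.16, percentile 11.5), and none passed 1.5-fold in either direction. SOD2 differed by 0.16 and ICAM1 by -0.14. The 8 members hold no cytokine or chemokine, since all those measured lay below the dim filter. The list median therefore does not describe cytokines. With no dim filter it was -0.07.

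Fatty acid synthesis genes, which include textbook targets of SREBP1, differed little. None of the 18 members past the filter reached 1.5-fold, and their median was -0.02 (interval -0.13 to 0.02, percentile 17.3). SCD, the stearoyl-CoA desaturase, came closest at -0.53, from 10.1 in the control to 9.62 in the knockdown. ACSL1, an acyl-CoA synthetase, differed by -0.35, whereas ELOVL5, a fatty acid elongase, differed by 0.47 and ACACA, the acetyl-CoA carboxylase, by 0.23. FASN and ACLY, named after their values were seen, differed by 0.11 and 0.06. After removal of a trend with gene length, an alternative chosen after seeing the data, the median became -0.07 and its percentile 1.48.

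Of the 16 cholesterol synthesis genes past the filter, 11 lay above 0 and 1 was at least 1.5-fold higher, MSMO1, a sterol C4-demethylase, at 0.67. ACAT2 differed by 0.56, SQLE, the squalene epoxidase, by 0.54 and HMGCS1, the cytosolic HMG-CoA synthase, by 0.47. The list median was 0.09 (interval -0.03 to 0.47, percentile 96.7), 0.06 with no dim filter and 0.15 with the stricter filter of 7.43. Removal of the length trend moved the percentile to 97.7. The sterol sensing and uptake list had a median of 0.04 (interval -0.14 to 0.09, percentile 74.9) with no member of 16 past 1.5-fold. In it SCARB1, the high-density lipoprotein receptor, differed by 0.42 and NPC2, a lysosomal cholesterol carrier, by -0.31. No probe set used here names HMGCR or LDLR alone.

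Targets of the liver X receptors, which respond to oxysterols, had a median of 0.20 over 6 members, at percentile 99.7, and the interval ran from -0.22 to 1.16. ABCA1 alone passed 1.5-fold, at 1.16, while LPCAT3 differed by 0.38, MYLIP by 0.22 and APOE by -0.22. The median was 0.09 with no dim filter and 0.30 with the stricter filter. That filter removes ABCA1, which ends the only call, and keeps only LPCAT3 and MYLIP. The glycerolipid and lipid droplet list had a median of 0.11 over 21 members (interval -0.03 to 0.18, percentile 99.4), with none past 1.5-fold, and a median of 0.05 with no dim filter. Its members GPAM and MGLL differed by 0.32 and 0.29, and LPIN1, a phosphatidate phosphatase, by -0.35. Fatty acid uptake and oxidation genes had a median of 0.06 over 25 members (interval -0.04 to 0.18, percentile 90.6), and PDK4 was the only member past 1.5-fold. The stricter filter removes PDK4 and gave a median of -0.02. ETFDH differed by 0.38 and SLC27A4 by -0.32.

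The other metabolic lists had medians within 0.07 of 0. The pentose phosphate and NADPH list had a median of -0.07 over 13 members (interval -0.14 to 0.04, percentile 2.34), and no member passed 1.5-fold. MTHFD2 differed by -0.29, RPIA by -0.26 and IDH1 by 0.28. Glycolysis genes had a median of 0.06 over 20 members (interval 0 to 0.14, percentile 86.1), with PFKFB3 at 0.48 and the glucose transporter SLC2A1 at 0.33. Of the 23 hypoxia response genes, 2 passed 1.5-fold, namely NDRG1 at 0.73 and EGLN3 at 0.71, both higher, and the list median was 0.06 (interval -0.01 to 0.19, percentile 88.0), against 0.17 with the stricter filter. Oxidative phosphorylation genes had a median of 0.02 over 33 members (interval -0.05 to 0.08, percentile 46.5), with NDUFB3 at -0.32. Ribosomal protein genes had a median of 0 over 47 members (interval -0.02 to 0.03, percentile 13.6), with the most distant member, RPL22, at 0.24.

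Of the 33 members of the list of the unfolded protein response and amino acid stress, 16 lay above 0 and 17 below. None was at least 1.5-fold higher and 3 were lower, PHGDH at -1.80, ASNS, the asparagine synthetase, at -0.92 and SLC7A5, a large neutral amino acid transporter, at -0.68. SHMT2, the mitochondrial serine hydroxymethyltransferase, differed by -0.41. The list median was -0.02 (interval -0.10 to 0.05, percentile 14.3), while its mean was -0.12. HSPA5, the main chaperone of the endoplasmic reticulum, and the transcription factor gene ATF4, both named after their values were seen, differed by 0.09 and 0.06.

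Few breast lineage genes differed by 1.5-fold. Of 30 oestrogen response genes, 1 was at least 1.5-fold higher, IGFBP5 at 0.61, and 1 lower, SLC7A5, and the median was 0.03 (interval -0.01 to 0.11, percentile 62.7). TFF3 differed by -0.49 and HSPB8 by 0.46, and ESR1, the oestrogen receptor gene, named after its value was seen, differed by 0.02. Among 25 luminal epithelial markers MUC1, a membrane mucin, was higher at 0.95 and ELF5, a luminal progenitor transcription factor, lower at -0.66, and the median was 0.06 (interval 0.01 to 0.20, percentile 86.5). TSPAN1 differed by 0.54. Few basal, mesenchymal or foreign markers passed the dim filter. The 7 basal and stem-like markers had a median of 0.11 (interval -0.04 to 0.30, percentile 94.5), with CD44 at 0.30, and with no dim filter the median turned to -0.04. Of the 11 mesenchymal genes TGFBI at 0.84 and ITGA5 at 0.64 passed 1.5-fold, with FN1, fibronectin, at 0.32, and the median was -0.01 (interval -0.17 to 0.64, percentile 41.2) against a mean of 0.10 and a median of 0.17 with the stricter filter, which leaves 1 member past 1.5-fold. The 13 matrix protease and migration genes had a median of 0.10 (interval -0.03 to 0.15, percentile 96.9), none past 1.5-fold, with ADAM10 at 0.41, and a median of 0 with no dim filter. Of 29 measured leukocyte, endothelial, fibroblast and other foreign markers, 2 passed the filter, CD68 at 0.28 and COL1A1 at 0.00, and their median was 0.14 (percentile 84.5).

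Proliferation genes as a list were near 0, with 2 of 39 members past 1.5-fold. These were the mitotic genes CENPE at 0.93 and CENPF at 0.63, both of which encode very long proteins, whereas UBE2C differed by -0.27 and MKI67 by 0.22. The stricter filter removes CENPE. The median was -0.02 (interval -0.06 to 0.06, percentile 10.2) against a mean of 0.02. Genes regulated by p53 had a median of 0.08 over 25 members (interval 0.02 to 0.30, percentile 97.3), none past 1.5-fold, against a median of 0.26 with the stricter filter. ZMAT3 differed by 0.55, EDA2R and TP53INP1 by 0.43 each and RRM2B by 0.41. With the length trend removed the p53 list moved to percentile 99.8. Apoptosis regulators had a median of 0.02 over 20 members (interval -0.09 to 0.07, percentile 63.9) against a mean of -0.02, with CYCS and BID both at -0.30.

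**Figure D3:**
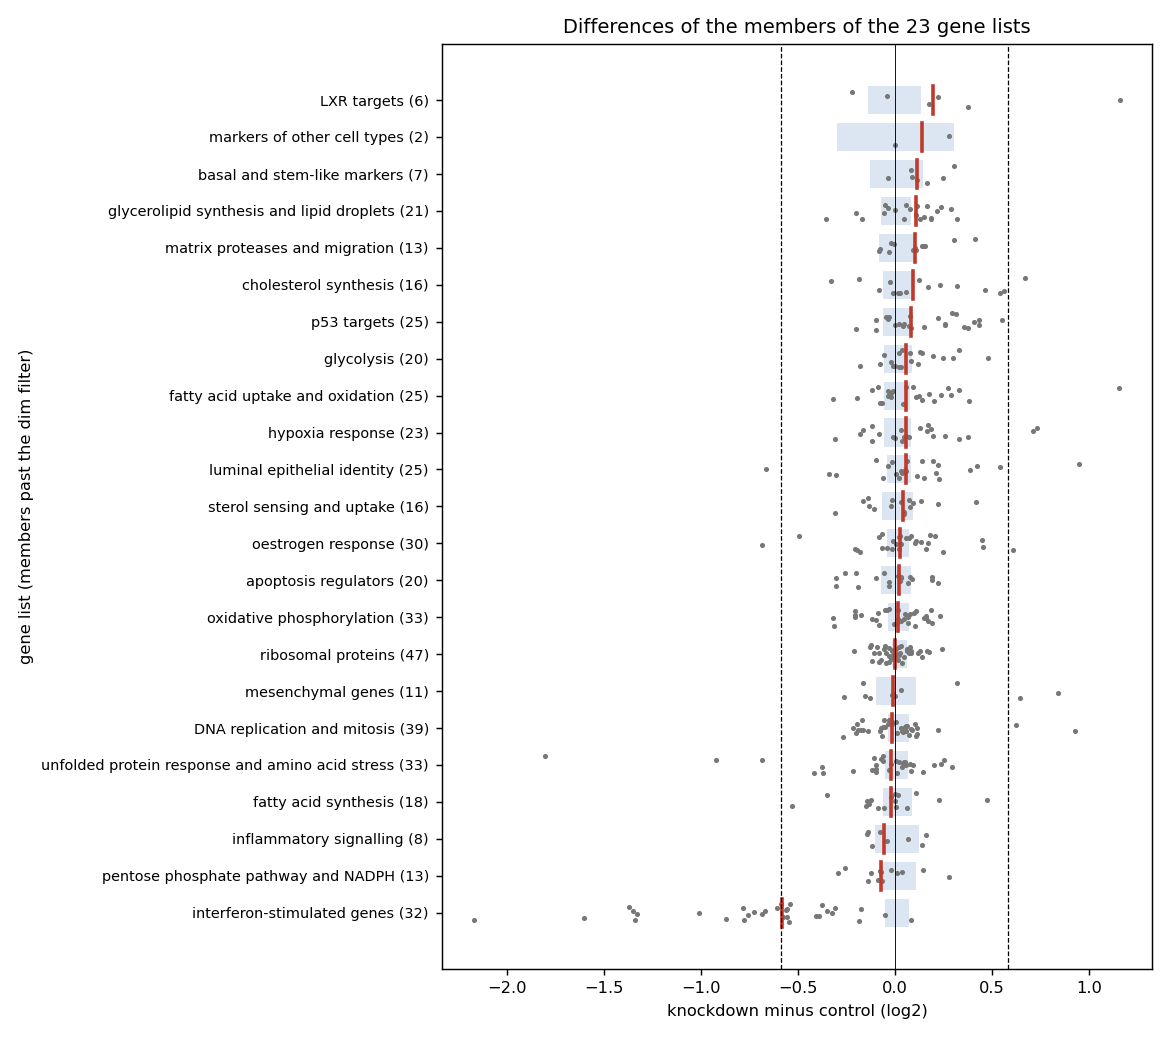
Differences between the knockdown and control arrays (log2, x axis) of the members past the dim filter in each of the 23 gene lists (y axis, number of members in brackets); points are genes, red bars list medians, shaded bands the central 95% of medians of 10000 random lists, and dashed lines 1.5-fold. The interferon-stimulated genes have their median at -0.58, far below their band of -0.05 to 0.07.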

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

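Probe sets outside the gene comparison also differed between the arrays. Among 1305 unnamed probe sets past the dim filter, 7 were at least 1.5-fold higher and 8 at least 1.5-fold lower in the knockdown array, with extremes of 1.01 and -1.20. Among 868 probe sets assigned to several genes, 3 were higher and 2 were lower. The 3 higher ones belong to the UGT2B glucuronosyltransferases, which conjugate steroids and share sequence, at 0.92 for UGT2B17 and UGT2B15 (2 probe sets with identical values) and 0.94 for a probe set that also covers UGT2B11, UGT2B10 and UGT2B7. The lower ones were shared by USP41P and USP18, at -1.05, and by a group of KIR receptor genes, at -0.89. These genes were named after their values were seen, and no explanation was tested.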

How the results depend on the processing

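SREBF1, at -0.94 to -0.92, and 20 of the 23 list medians stayed within their spread under every alternative run that kept them. The stricter dim filter, at 7.43, removes SREBF1, whose higher value was 7.39, and so ends its call. Of 1207 further comparisons of named genes and list members, 1202 stayed so. The other 5 were counts of list members that moved between 0 and 2 under other dim filters. Part of this agreement was fixed in advance. A gene with 1 probe set, such as SREBF1, reads the same under either probe set choice, and a dim filter changes no gene's difference. No called value changed sign. Medians near 0, and those of short lists under other dim filters, turned or moved by over 1.5 times without leaving their interval, apart from the lists named below; the larger moves stand beside their results. The size-rule counts depended on the threshold and the filter. The 61 genes higher became 14 at 2-fold, 146 at 3 local spreads and 39 with the stricter dim filter, and the 46 genes lower became 12 at 2-fold, 115 at 3 local spreads and 72 with no dim filter; these follow from the construction of each rule. Of the 107 genes called, 105 remained after centring, 99 after removal of the intensity trend, 101 after quantile normalisation and 97 after removal of the gene span trend. The stricter dim filter, which drops genes, left 70 of them. No setting moved the median of all retained genes beyond 0.022. The mean of the unfolded protein response and amino acid stress list was -0.12 against a median of -0.02, with 3 members at -0.68 or lower. The ribosomal protein median moved from 0 to 0.047 with the gene span trend removed; the cause was not tested. The median of the markers of other cell types was 0 with no dim filter, when members below the filter enter. With the span trend removed, the fatty acid synthesis list went from percentile 17.3 to 1.48, cholesterol synthesis from 96.7 to 97.7 and p53 targets from 97.3 to 99.8. With the intensity trend removed, p53 targets reached 99.9. No paired analysis was possible because each group holds 1 array, and for the same reason no replicate could be left out. Without detection calls, the background level of dim genes is unknown.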

Other observations

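Of the tests in this part, those of the neighbouring genes, of the mitotic list, of the chaperones, of the intensity trend and the span trend on long coiled-coil genes as a whole and of the number of lines were chosen only after the result was seen, as were the genes in the 7 further lists and the removal of the gene span trend.

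Of 5 metallothioneins, small metal-binding proteins, 1 was at least 1.5-fold lower in the knockdown array, MT2A at -0.84. MT1G differed by -0.48, MT1X by -0.43 and MT1F by -0.42, whereas MT3 differed by 0.03, and the median of these 5 was -0.43 (interval -0.84 to 0.03). The members are near-identical and can share probe signal, so they are not independent readings. Of 10 mucins and mucosal secretory genes, 4 were at least 1.5-fold higher, namely MUC1 at 0.95, MUC5B at 1.01, BPIFB1 at 0.89 and MSMB at 2.31, and all 4 had been seen before the list was written. The list median of 0.34 (interval -0.20 to 1.01) is not independent of them. MUC20 differed by 0.45, and 3 members lay below 0, WFDC2 at -0.26, GALNT6 at -0.20 and GALNT7 at -0.08. Of 14 further interferon signalling and RNA silencing components outside the fixed list, none passed 1.5-fold. Their median was -0.04 (interval -0.13 to 0.14), with TRIM56 at -0.31, JAK1 at 0.09, TYK2 at -0.09, IRF3 at -0.13 and CGAS at -0.08. Sensors and transcription factors that are themselves in the fixed list were left out of these 14, and RIGI differed by -0.55, IFIH1 by -0.56, EIF2AK2 by -0.39, IRF7 by -0.40 and IRF9 by -0.31.

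A run of 6 neighbouring genes lay above 0. C12orf60, SMCO3, ART4, MGP, ERP27 and ARHGDIB, which follow each other in the GRCh38.p14 annotation, differed by 1.01, 0.58, 1.59, 0.69, 0.52 and 0.56. SMCO3 and ARHGDIB lay below the dim filter in both arrays. The window median of 0.64 was the highest of 18223 windows of 6 consecutive measured genes, shared with overlapping windows, and when gene order was shuffled 1000 times the highest window reached it in 1 shuffle. The window size was chosen after the run was seen.

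Among 24 textbook interferon targets outside the fixed list and past the dim filter, none passed 1.5-fold, 21 lay below 0 and the median was -0.20 (interval -0.32 to -0.05), lower than in all 10000 random lists, with PLSCR1 at -0.50 and TAP2 at -0.42. Removal of the intensity trend left the fixed list's median at -0.60 and removal of the gene span trend left it at -0.60, so neither trend accounts for the pattern. Whether the control carries a hairpin is not settled. With 1 line per group, loss of SREBP1 cannot be told apart from any other difference between the 2 lines, whichever line it arose in. Examples are a response of the control line to its vector or hairpin and drift between separately kept lines.

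ATF4 is the transcription factor of the amino acid response. A list of 25 genes of amino acid synthesis and transfer RNA charging outside the fixed list was taken to stand for its targets. Not every member is an established target. Of these genes, 22 lay below 0 and none passed 1.5-fold, with a median of -0.23 (interval -0.34 to -0.11), lower than in all 10000 random lists. PYCR1 differed by -0.53, YARS1 by -0.49, PCK2 by -0.43 and PSPH by -0.40. With the gene span trend removed the median was -0.24, which argues against the gene span trend as the source. The 17 chaperone genes had a median of 0.052 (interval 0.01 to 0.15, percentile 81.8), so they were not lower as a set. Of these, 15 were members of the fixed lists whose values had been seen. The comparison is therefore no independent test of a shift of the whole endoplasmic reticulum stress response. The values are consistent with a lower ATF4 programme as a hypothesis; a difference in medium, density or passage between the 2 cultures was not tested and stays open.

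Among the genes past 1.5-fold, 8 that encode very long coiled-coil proteins were noticed first, AKAP9, CENPE, KIF20B, GCC2, ANKRD26, GOLGB1, TPR and CENPF, at 0.63 to 1.13. A further 35 such genes, of which GOLGA4 at 0.62 also passed 1.5-fold, had a median of 0.20 (interval 0.14 to 0.28), higher than in all 10000 random lists, as a difference in RNA integrity or labelling that favours long transcripts predicts. Across the 9397 retained genes with a span, the difference was larger at a longer log10 gene span (Spearman's rho 0.225, Pearson's r 0.202, across genes, which are not independent replicates), from a median of -0.07 in the 10% of genes with the shortest span to 0.06 in the 10% with the longest. Removal of the intensity trend left the further genes at a median of 0.18 (interval 0.12 to 0.29), which argues against an intensity bias. The mitotic list, which also holds DNA replication genes, had a median of -0.015 (interval -0.06 to 0.06). Proliferation genes as a whole were thus near 0. Because the list is mixed and its value was known when the limit was set, it cannot tell whether mitotic genes alone shifted. Removal of the gene span trend took GOLGA4 from 1.53-fold to 1.48-fold (0.62 to 0.56, local spread 0.14 in each), just under the threshold. It left the further genes at 0.14 (interval 0.11 to 0.25), higher than in all 10000 random lists. This value lay between the limits written before the test was run, so that test could not tell. The fitted span trend thus did not take up the whole rise of the further genes. The limit that would count this against the span trend as the whole cause was chosen after the result was seen, so it decides nothing. All 43 lay at 0.22 (interval 0.12 to 0.35), also higher than in all 10000 random lists. They include the 8 picked for their size, so their value adds no support. The span trend, and an effect of transcript length, which was not analysed here, stay open beside a biological change.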
